A study of Drosophila melanogaster with 8 samples.

How the data were processed

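The series held 8 two-colour Agilent oligonucleotide arrays of adult Drosophila melanogaster RNA in 2 sets of 4. Per the labels, the first set placed RNA of mature w1118 males fed 5% sucrose with 0.3% phenobarbital (PB) for 6 h in the Cy5 channel, against RNA of w1118 males fed 5% sucrose alone (the vehicle) in Cy3. The second set placed RNA of HS-CncC flies in Cy5 against RNA of w1118 flies in Cy3, both taken after 30 min at 37 °C and 2 h of recovery at room temperature. HS-CncC flies overexpress CncC, a long isoform of the transcription factor gene cnc, per the series title, and w1118 is a white-eyed laboratory strain. The labels give the sex of the flies for the PB set; the sex of the heated flies is not given in the sources used here. Flies were raised on cornmeal, molasses and agar food, and total RNA was isolated with Tripure and column purified, per the labels' protocols. Labelled cRNA was primed from oligo dT with a T7 promoter, per the labels' protocols, so transcripts without a poly(A) tail are poorly represented.

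The scanner files deposited by the authors hold fluorescence intensity per spot in arbitrary units for both channels, with local background, Agilent's background-subtracted and dye-normalized processed intensity, and quality marks. A deposited log10 ratio of the processed intensities was not used. The submitters' processing notes name Agilent Feature Extraction 9.5.1.1, whereas the file headers name version 10.5.1.1 and genome build dm3. The authors also deposited a table of log2 values per probe. Set against the scanner files, that table equalled log2 of processed Cy5 over processed Cy3, with r of at least 0.9999 on each array, so its scale and direction are settled and no centring was applied; its array medians lay between 0.019 and 0.072. Every ratio below is log2 of the PB or HS-CncC sample over its control on the same array. No array had its dyes swapped, so a dye preference of a probe is part of its ratio in both sets and cancels only in the difference between sets.

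Each array held 45020 spots, of which 1417 were control spots, and 32162 probes for transcripts. Through locus tags, symbols and accessions, 20972 probes were matched to 1 gene of the reference table of the Release 6 assembly, which was used for names only; 174 probes kept only the name given by the array design, 11016 had no gene name and are given by their identifier, and 155 had accessions of several genes. Coordinates are those of the probes in the files, on dm3. With no genome sequence or annotation of that build used here, exon or untranslated region positions are not given. Between 33348 and 37444 of 43603 transcript spots were well above background per array and channel, the red (Cy5) counts being the lower ones on every array, and no transcript spot was saturated.

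Mean spot intensity was corrected with the median local background by normexp with an offset of 50, then normalized within each array by loess, with control spots and spots marked as outliers given no weight (limma 3.58.1 in R 4.3.3). Outlier spots were then left out and the spots of a probe averaged. A gene was represented by its probe with the highest mean intensity over the 8 arrays, and a probe without a gene name stood for itself; both are called features. A feature entered a comparison if well above background in at least 1 channel on at least 3 of its 4 arrays. Log2 ratios were tested against 0 in separate limma fits of the 4 arrays of each set, and the difference between sets in a fit of all 8, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Every adjusted p of a gene or feature below comes from these limma fits. Errors are SDs between arrays, and n is the number of arrays. The labels do not say that the replicates came from separate groups of flies, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: changes of simulated data with a true log2 change of 0.5, 1 and 2 were recovered for 68.7%, 88.1% and 98.5% of features with the PB spread, 65.7%, 89.6% and 92.4% with the HS-CncC spread, and 61.9%, 90.3% and 97.0% for the difference. In the same simulations 4.0%, 4.6% and 8.0% of the calls were false. Of 18649 features simulated with the PB spread 18449 were left unchanged, and noise was independent between features. A larger share was called in the real data, so these rates need not hold there. A feature not well above background on all 4 arrays of one sample has only a bound, which is open to dye bias. It is given as at least N-fold between channel levels after loess and quantile normalization of average intensity. The dim level was the measured one or the lowest level well above background on that array and channel, whichever was higher. The bound is a mean over arrays, so single arrays may lie below it.

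Before the data were examined, 25 gene lists were fixed: cytochrome P450, glutathione S-transferase (GST), UDP-glycosyltransferase (UGT), esterase and epoxide hydrolase, ABC transporter, Keap1/CncC antioxidant, heat shock, proteasome, antimicrobial and immune, Turandot stress, digestive enzyme, fasting-induced, lipogenic, circadian clock, ecdysone response, activity-regulated, ribosomal protein, accessory gland, testis, ovary and yolk, eye, muscle, fat body, hemocyte and Malpighian tubule genes. The last 8 name tissues. Shifts of lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over 49 tests (25 lists in 2 comparisons, less 1 list with too few complete members), and again with an estimated correlation. With the preset value 16 tests passed and with the estimated correlation 0 did. The method fry, which tests each list's own genes without comparing them with others, passed 27 but not 4 of those 16. At an unadjusted p under 0.05 the preset tests numbered 22 and those with an estimated correlation 2. On simulated data the 1 list of 30 genes shifted by a log2 of 0.3 was called and none of 24 unshifted lists was. The simulated genes varied independently, whereas the estimated correlation of real lists reached 0.75, in accessory gland genes with PB. The simulation therefore cannot show whether the preset value suits the real lists.

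The genes named were set by a rule made before the data were examined. It took, per comparison, the 12 largest rises and 8 largest falls among features past the threshold with 1 sign on all 4 arrays and both channels well above background on at least 3; the 3 largest bounds each way; up to 4 called members per list with the largest absolute change; the 6 largest differences each way past the threshold; and 20 genes fixed by name (cnc, w, Keap1, Gclc, Gclm, Hr96 and P450, GST and epoxide hydrolase genes). After the data were examined, the 6 largest differences each way among features well above background in both channels on at least 6 of the 8 arrays were added. Of the genes so chosen, 1 is not reported here. Alternatives covered the background correction, the offset, median centring in place of loess, Agilent's processed intensities, the deposited log2 table, quantile normalization of average intensity, the filter on dim probes, the mean over the probes of a gene, eBayes with a trend, a fit of all 8 arrays, a 1.5-fold threshold, an adjusted p under 0.01, base composition of the probes, the replicate number as a block, and leaving out each array. Figures were drawn with matplotlib 3.10.9.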

Results

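Transcript levels were compared in adult Drosophila melanogaster on 8 two-colour arrays. On 4 arrays, w1118 males fed phenobarbital (PB), a barbiturate widely used to induce detoxification enzymes, were set against vehicle-fed w1118 males. On the other 4, heated HS-CncC flies were set against heated w1118 flies. CncC is the fly counterpart of the mammalian antioxidant regulator Nrf2. The stated purpose was to identify expression changes in response to PB and to CncC overexpression. The median signal of the green channel, which held the controls, lay between 134.8 and 262.5 per array, over mean backgrounds of 12.4 to 15.7. That of the red channel lay between 280.6 and 598.2, over mean backgrounds of 55.1 to 62.3. After filtering, 18649 features were tested for PB, of which 12417 were named genes, and 18312 for HS-CncC, of which 12342 were. Correlations between arrays, taken across features, ran from 0.55 to 0.802 within the PB set, where array 1 gave the lowest values. Within the HS-CncC set they ran from 0.859 to 0.881.

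The comparison of PB with vehicle asked which transcripts a 6 h PB meal changed. The probe listed for Cyp12d1-d, a mitochondrial cytochrome P450 gene, rose by a log2 of 6.22 ± 0.12 (SD, n = 4, adjusted p = 9.12e-08) but carried accessions of several genes. The P450 gene Cyp6a8 rose by 5.63 ± 0.27 (n = 4). CG6908, a member of the ecdysteroid kinase-like family, rose by 5.54 ± 0.06 (n = 4), the glutathione-conjugating GstD7 by 4.68 ± 0.28 (n = 4), and the glycosyltransferase Ugt35C1 by 4.03 ± 0.20 (n = 4). Among features that met the naming rule, the largest falls were those of phu (-3.28 ± 0.35, n = 4, adjusted p = 2.68e-05) and of CG11892 and CG10514, also ecdysteroid kinase-like genes (-3.08 ± 0.60 and -2.82 ± 0.56, n = 4 each). Lsd-1, a perilipin that coats lipid droplets, fell by 2.41 ± 0.18 (n = 4). In all, 1879 features were higher and 2621 lower with PB, or 24.1% of those tested. Of these, 248 and 431 changed at least 1.5-fold, and 127 and 104 at least 2-fold.

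The 20 genes fixed by name rose with PB, except Hr96 and w. Keap1, which encodes the inhibitor of CncC, rose by a log2 of 2.17 ± 0.03 (n = 4, adjusted p = 2.6e-06). Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, rose by 1.33 ± 0.16 and its modifier subunit gene Gclm by 0.55 ± 0.08 (n = 4 each). The P450 genes Cyp6w1, Cyp6a21, Cyp6a2 and Cyp6d5 rose by 4.53, 4.47, 4.27 and 4.05, and the probe listed for Cyp12d1-p by 5.47. The Cyp6g1 probe used rose by 2.12, whereas its other probes gave 0.10 and -0.07, and the mean over them was 0.72. The GST genes GstD2, GstD1 and GstE1 rose by 4.41, 2.11 and 1.18, and Jheh1 and Jheh2, juvenile hormone epoxide hydrolases, by 3.40 and 2.85. The cnc probe used was higher by 0.58 ± 0.18 (n = 4, adjusted p = 0.00426), whereas a cnc probe of another transcript gave -0.07 ± 0.24. The mean over the cnc probes was 0.18 with PB and was not called (adjusted p = 0.0633). Hr96, a nuclear receptor for xenobiotics, was not called (-0.07 ± 0.17, n = 4, adjusted p = 0.552), and neither was w, the white eye-colour gene (-0.03 ± 0.08, n = 4, adjusted p = 0.738). The probes used for Cyp12d1-d and Cyp12d1-p, near-identical neighbouring genes, carried accessions of several genes, so their values cannot be assigned to either gene. Another Cyp12d1-d probe, not well above background on any array, gave 0.04 with PB and 0.21 in HS-CncC flies.

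**Figure D1:**
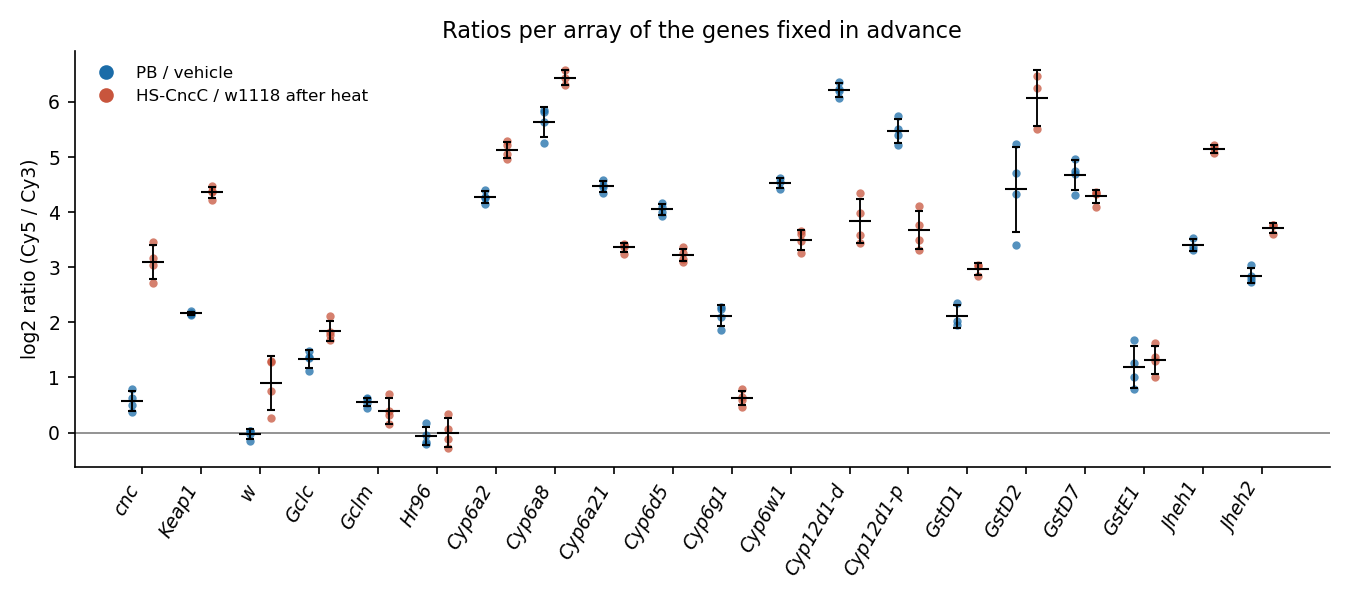
Log2 ratio of the treated over the control sample on each array (dots) with the mean ± SD (black bars) for the 20 genes fixed by name, PB arrays in blue and HS-CncC arrays in red. The Cyp12d1-d probe, which cannot be assigned to 1 gene, rose more with PB (6.22 against 3.84), Keap1 rose more in HS-CncC flies (4.36 against 2.17), and Hr96 lay near 0 in both sets.

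Many detoxification genes rose with PB. Of 38 measured GST genes, which conjugate glutathione to reactive compounds, 20 were higher and 2 lower (23 and 6 adjusted over the list alone), among them GstE3, which rose by 3.77 ± 0.22 (n = 4). Of 30 UGT genes, which attach sugars to lipophilic compounds, 12 were higher and 3 lower (12 and 5 adjusted over the list alone). Ugt37A2, Ugt37E1 and Ugt37B1 rose by 3.57 ± 0.20, 2.99 ± 0.07 and 2.30 ± 0.19 (n = 4 each). The GST list had a median of 0.37 and a camera adjusted p = 4.76e-07. The UGT list had a median of 0.03, which became -0.01 once base composition was removed, and a camera adjusted p = 0.00244. Both lists had an adjusted p = 0.666 with an estimated correlation. Of 77 P450 genes 26 were higher and 17 lower (30 and 19 adjusted over the list alone), with a median of 0.06 and a camera adjusted p = 0.00304. The P450 list had an adjusted p = 0.673 with an estimated correlation, and without the filter on dim probes its preset value was 0.0762.

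Other genes of detoxification and redox defence moved both ways with PB. Of 34 Keap1/CncC antioxidant genes 11 were higher and 8 lower (12 and 8 adjusted over the list alone), with a median of 0.08 and a camera adjusted p = 0.0631. The list test passed with an offset of 0 (0.0354), with median centring (8.09e-06, with a median of 0.25) and without array 2 (0.0417), array 3 (0.0281) or array 4 (0.0278). The list median was 0.22 on array 1 against a mean of 0.02 on the other arrays. MsrA, a methionine sulfoxide reductase gene, rose by 2.69 ± 0.21 (n = 4). Esterase and epoxide hydrolase genes had 7 of 19 higher and 6 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.473). ABC transporter genes had 4 of 16 higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.72). The multidrug resistance genes MRP and Mdr50 rose by 2.11 ± 0.27 and 1.37 ± 0.09 (n = 4 each). An MRP probe of another transcript gave 0.71 ± 0.20.

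Genes of fat synthesis fell with PB. Of 16 lipogenic genes 10 were lower and 3 higher (11 and 3 adjusted over the list alone), with a median of -0.78 and a camera adjusted p = 0.00164. The list had an adjusted p = 0.666 with an estimated correlation. FASN1, a fatty acid synthase gene, fell by 1.95 ± 0.11 (n = 4, adjusted p = 9.96e-06), the desaturase gene Desat1 by 1.44 ± 0.20 (n = 4), and ACC, which encodes acetyl-CoA carboxylase, by 1.38 ± 0.01 (n = 3). Dgat2, which acts in triglyceride synthesis, rose by 2.25 ± 0.35 (n = 4). Pepck1, a phosphoenolpyruvate carboxykinase gene of the fasting-induced list, rose by 2.92 ± 0.30 (n = 4), and sug, a transcription factor gene of that list, fell by 1.18 ± 0.20 (n = 4). The fasting-induced list had 6 of 15 genes higher and 4 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.212).

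Immune and blood cell genes were more often lower than higher with PB. Of 37 antimicrobial and immune genes 16 were lower and 2 higher (20 and 2 adjusted over the list alone), with a median of -0.45 and a camera adjusted p = 0.000169. Of 12 hemocyte markers 8 were lower and 1 higher, with equal counts adjusted over the list alone, a median of -0.40 and a camera adjusted p = 0.00518. Both lists had an adjusted p = 0.666 with an estimated correlation. The attacin gene AttA was lower by a log2 of -1.55 ± 0.96 (n = 4, adjusted p = 0.0185), a call lost without array 2 (0.0631) or array 4 (0.0638) and with an offset of 0 (0.0502). The hemocyte markers that fell included the prophenoloxidase gene PPO1 (-1.76 ± 0.46, n = 4) and the phagocytosis receptor gene eater (-0.98 ± 0.15, n = 4). They also included the collagen IV genes vkg and Col4a1 (-0.96 ± 0.20 and -0.81 ± 0.21, n = 4 each), which the fat body expresses too. The other probes listed for vkg lie on 2R, away from the probe used on 2L, and gave 0.02 and 0.13, so that the mean over probes was -0.27. Npc2d, a gene of the fasting-induced list and not of these lists, fell by 1.79 ± 0.44 (n = 4).

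Of 92 ribosomal protein genes 44 were higher and 4 lower with PB (44 and 5 adjusted over the list alone), with a median of 0.17, which became 0.72 with median centring, and a camera adjusted p = 6.31e-09. They had an adjusted p = 0.666 with an estimated correlation, and RpS25 rose by 0.74 ± 0.17 (n = 4). Of 26 testis genes 9 were higher and 0 lower by limma (12 and 0 adjusted over the list alone, 13 and 0 at an unadjusted p under 0.05), with a median of 0.17 and a camera adjusted p = 0.000532. They had an adjusted p = 0.716 with an estimated correlation, and Mst87F, a sperm tail protein gene, rose by 0.60 ± 0.18 (n = 4). On array 1 the testis median was -0.03, against a mean of 0.26 over the other arrays. Of 19 heat shock genes 3 were higher and 0 lower by limma (2 and 0 adjusted over the list alone, 6 and 1 at an unadjusted p under 0.05), with a median of 0.21 and a camera adjusted p = 0.0364. That list had an adjusted p = 0.716 with an estimated correlation. Its preset call was lost without array 1 (0.401), without array 3 (0.0778), with no background subtraction (0.0758), the mean local background (0.12), the processed intensities or the deposited table (0.189 with each), the mean over probes (0.167) and all 8 arrays in one fit (0.139), and without the filter on dim probes (0.173).

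Of 22 muscle genes 1 was higher and 7 lower with PB (2 and 7 adjusted over the list alone, camera adjusted p = 0.314), with a median of -0.04 that became 0.28 with median centring. The muscle list passed in that upward direction with median centring (0.0451) and downward with the processed intensities and the deposited table (0.0206 with each). The flight muscle genes Act88F, fln and TpnC4 fell by 2.16 ± 0.97, 1.63 ± 0.21 and 1.03 ± 0.22 (n = 4 each). Digestive enzyme genes had 12 of 45 higher and 12 lower (14 and 14 adjusted over the list alone, camera adjusted p = 0.91), eye genes 5 of 21 and 2 (8 and 2, 0.108), and Malpighian tubule genes 3 of 14 and 5 (3 and 6, 0.812). Proteasome genes had 6 of 44 higher and 5 lower, as over the list alone (0.825). Of 11 clock genes 1 was higher and 2 lower, as over the list alone (0.766), and cwo, a repressor gene of the clock, fell by 1.21 ± 0.30 (n = 4) at the probe used, while its other probes gave -0.48, -0.37 and -0.32. Ecdysone response genes had 1 of 16 higher and 2 lower (1 and 2, 0.931), accessory gland genes 1 of 25 and 1 (0 and 1, 0.577), ovary and yolk genes 2 of 21 and 2 (2 and 2, 0.473), and fat body genes 1 of 11 and 1 (1 and 1, 0.72). Activity-regulated genes had 0 of 10 higher and 2 lower by limma (1 and 4 adjusted over the list alone, as at an unadjusted p under 0.05, camera adjusted p = 0.208). Of these lists, the proteasome and eye lists passed with median centring (2.05e-05 and 0.000631, with medians of 0.17 and 0.23), and the eye and accessory gland lists without array 4 (0.0398 and 0.00713). The Turandot stress genes had 0 of 6 called, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.931). Median, mean and test differed in sign for the ABC transporter, proteasome, Turandot, digestive enzyme and ecdysone lists with PB.

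Bounds were small with PB, for features not well above background in 1 of the samples. The probe A_09_P194990 was at least 1.5-fold higher (adjusted p = 0.00152) and TC243295 at least 1.3-fold (adjusted p = 0.00775). CG4830 (adjusted p = 0.0371), Mos (adjusted p = 0.0157) and A_09_P124395 (adjusted p = 0.05) were at least 1.2-fold lower. The lower calls of CG4830, Mos and A_09_P124395 were lost without array 2 (0.142, 0.0755 and 0.197) or array 3 (0.157, 0.0826 and 0.0531). Those of CG4830 and A_09_P124395 were also lost without array 4 (0.117 and 0.152), and that of A_09_P124395 without array 1 (0.0852). With median centring the calls of TC243295 (0.116) and A_09_P124395 (0.0678) were lost, with a trend and a robust fit that of A_09_P124395 (0.0569), and with all 8 arrays in one fit that of CG4830 (0.122). The counts for PB depended on single arrays: 3139 features were higher and 3210 lower without array 1, 459 and 891 without array 2, 598 and 1163 without array 3, and 958 and 1744 without array 4. With all 4 arrays and the threshold kept, the count of higher features ran from 1244 with no offset to 3737 without the filter on dim probes, and with median centring 54.4% of the calls were higher, against 41.8% with loess.

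**Figure D2:**
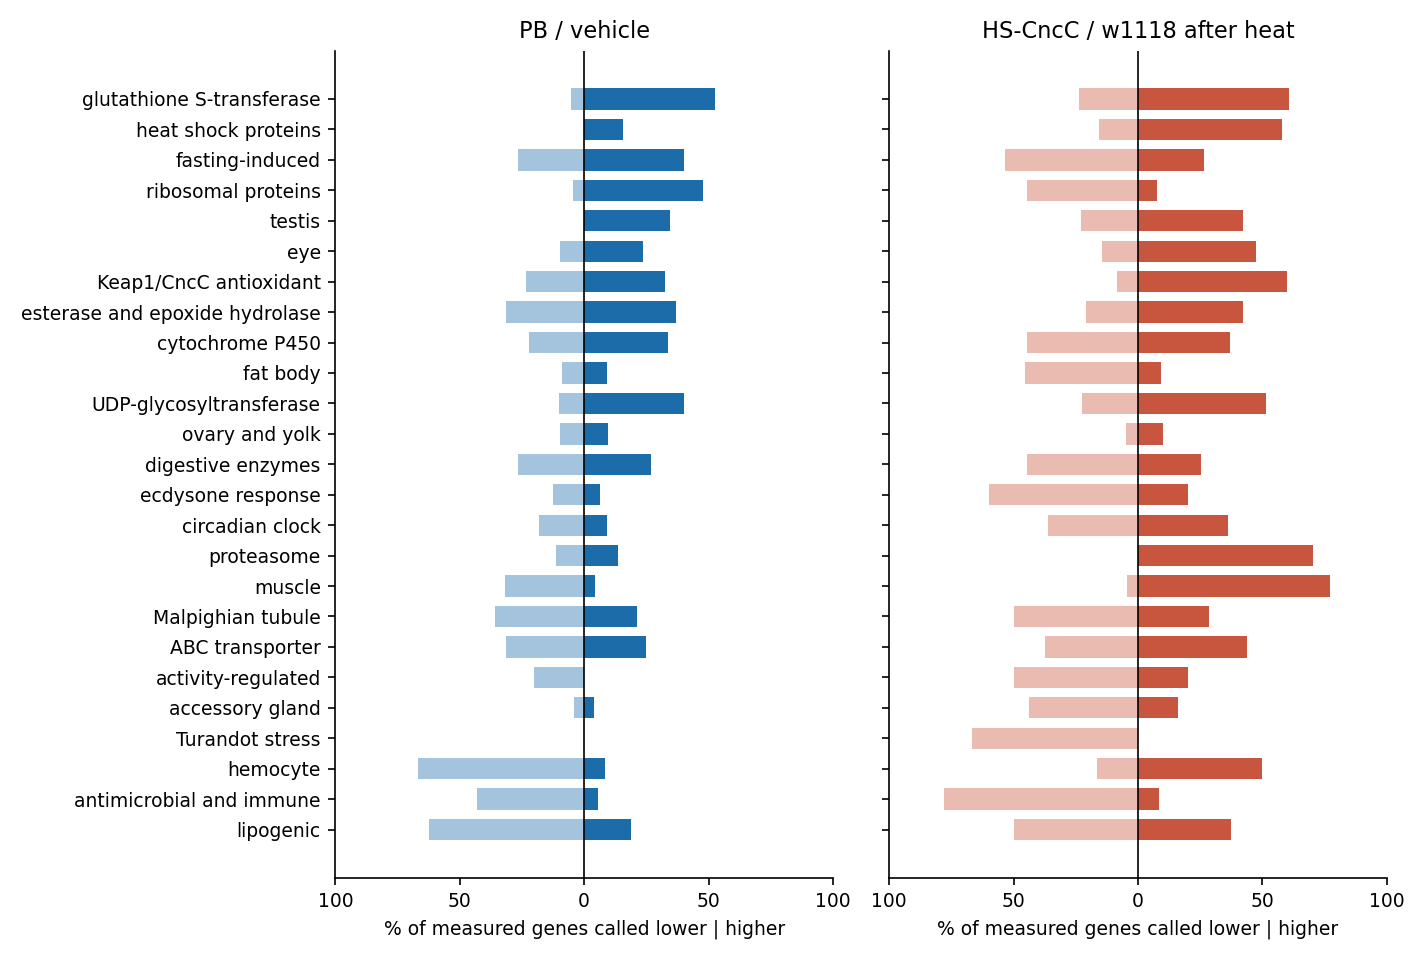
Percent of the measured genes of each of the 25 lists called lower (light bars, leftward) and higher (dark bars, rightward), with PB on the left and in HS-CncC flies on the right, ordered by the median log2 ratio with PB. Lipogenic genes were mostly lower with PB (10 of 16), GST genes were more often higher than lower in both comparisons (20 and 23 of 38 higher), and proteasome genes were mostly higher in HS-CncC flies (31 of 44).

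The comparison of heated HS-CncC with heated w1118 flies asked which transcripts changed with CncC overexpression. The cnc probe used (3R, 19012519 to 19012578, dm3) was higher by a log2 of 3.10 ± 0.31 (SD, n = 4, adjusted p = 9.24e-06). Keap1 rose by 4.36 ± 0.10 (n = 4, adjusted p = 3.19e-07). Large rises were those of Cyp6a8 (6.44 ± 0.14, n = 3), GstD2 (6.08 ± 0.51, n = 3), the ecdysteroid kinase-like gene CG6908 (5.87 ± 0.08, n = 3), Jheh1 (5.15 ± 0.07, n = 3) and Cyp6a2 (5.13 ± 0.15, n = 4). Prx3, a mitochondrial peroxiredoxin gene, rose by 5.21 ± 0.05 (n = 4), whereas the attacin gene AttA fell by 4.74 ± 0.84 (n = 4) and tobi, an insulin-responsive glucosidase gene, by 3.81 ± 0.06 (n = 4). A cnc probe of another transcript (3R, 19047983 to 19048042) gave -0.56 ± 0.27, and one more cnc probe was not well above background, so the mean over the cnc probes was 0.90. The samples differ in strain, so genetic background is part of every ratio, whereas the heat treatment was common to both.

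In all, 4182 features were higher and 4894 lower in HS-CncC flies, or 49.6% of those tested, of which 1206 and 1335 changed at least 1.5-fold and 542 and 409 at least 2-fold. Among features that met the naming rule, the largest rises were those of CG31226 (7.66 ± 0.18, n = 4) and the unnamed feature TC255103 (7.45 ± 0.30, n = 4). Neither was far enough above background to be tested with PB. The trypsin genes lambdaTry (5.41 ± 0.14, n = 3) and epsilonTry (4.61 ± 0.27, n = 4) also rose, as did CG9360 (5.03 ± 0.05), CG14132 (4.68 ± 0.19), Dgat2 (4.53 ± 0.14), MsrA (4.34 ± 0.16) and CG10550 (4.24 ± 0.14). GstO3, an omega class GST gene, rose by 4.04 ± 0.27 (n = 3). Large falls were those of IP14124 (-5.13 ± 0.54, n = 4), CG12934 (-4.67 ± 0.38), the diptericin gene DptA (-3.68 ± 1.14), the attacin gene AttC (-3.57 ± 0.61), CG3739 (-3.50 ± 0.29) and BaraA1, an antimicrobial peptide gene (-3.43 ± 0.50). Features not well above background in w1118 gave bounds: TC240329 was at least 19.8-fold (adjusted p = 0.00463), EC196523 at least 8.6-fold (adjusted p = 1.53e-06) and AT01131 at least 6.5-fold higher in HS-CncC flies (adjusted p = 2.08e-05). The dim levels of TC240329, EC196523 and AT01131 were the measured ones, so these bounds equal the mean measured ratios. The bound of TC240329 had a log2 SD of 2.29, with a ratio of 0.90 on array 4 against a mean of 5.44 on the others. It was 43.5-fold without array 4, 16.7-fold without array 1 and 14.5-fold without array 2 or array 3. Its call was lost with a trend and a robust fit (0.0523). CG30049, CG9826 and CG42460 were at least 2.9-fold (adjusted p = 0.00246), 2.3-fold (adjusted p = 0.00167) and 1.8-fold lower (adjusted p = 0.00129). Without array 4 the bound of CG30049 was 2.4-fold. Without the filter on dim probes 6323 features were higher and 4973 lower, and with median centring 5186 were higher and 4245 lower, so that 55% of the calls were higher, against 46.1% with loess.

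Probes of 1 transcript disagreed most often on chromosome arm 2R in HS-CncC flies. On 2R 32 of 873 transcripts, or 3.67%, had probes at least 1 log2 unit apart, against 29 of 3306, or 0.88%, on the other arms (Fisher's exact test, two-sided, p = 4.19e-08). With PB the numbers were 3 of 875 and 12 of 3346 (Fisher's exact p = 1). The arm was singled out after the data were seen, and neighbouring transcripts were counted as independent. The Cyp6g1 probes were the farthest apart in HS-CncC flies. The probe used (2R, 8074216 to 8074275) gave 0.62 ± 0.13, and probes at 8075583 to 8075642 and 8075872 to 8075931 gave 5.57 ± 0.14 and 6.70 ± 0.28. With PB the same probes of Cyp6g1 gave 2.12 ± 0.19, 0.10 ± 0.22 and -0.07 ± 0.28. In HS-CncC flies the probes of the trypsin gene deltaTry ran from -2.54 to 0.96, and those of trpl, a light-activated channel gene, from -1.29 to 1.14. The eye-colour gene w was higher by 0.90 ± 0.49 (n = 4, adjusted p = 0.00595) at the probe used and by 0.28 ± 0.20 at its other probe. Over the alternatives w ran from 0.59 with the mean over probes to 3.07 with the processed intensities.

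**Figure D3:**
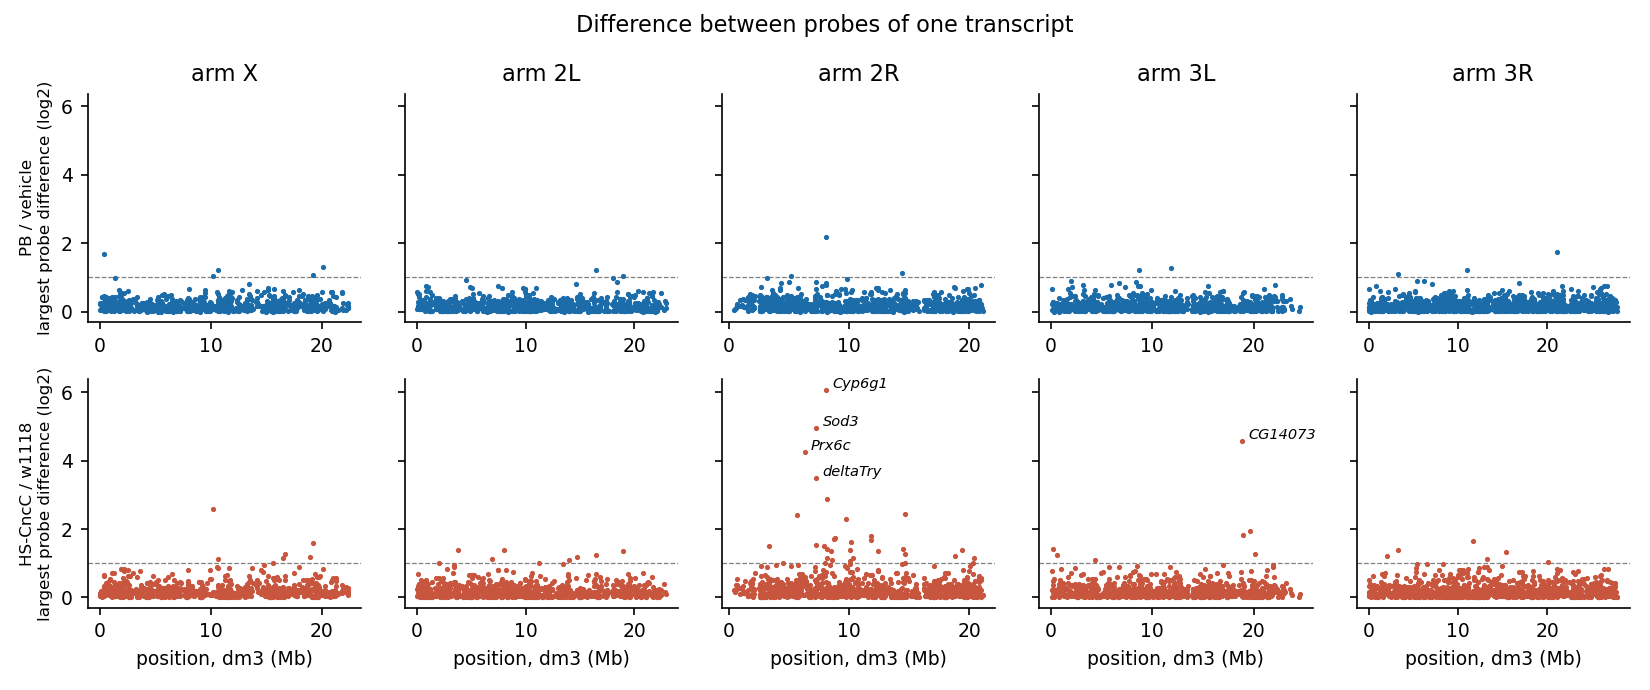
Largest difference in log2 ratio between the probes of 1 transcript, by position in Mb along the 5 major chromosome arms, with PB in the top and HS-CncC in the bottom panels and a dashed line at 1 log2 unit. Transcripts above the line were most frequent on arm 2R in HS-CncC flies (32 of 873), led by Cyp6g1 with a difference of 6.08.

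Antioxidant and proteasome genes rose in HS-CncC flies. Of 35 Keap1/CncC antioxidant genes 21 were higher and 3 lower, with equal counts adjusted over the list alone, a median of 0.39 and a camera adjusted p = 7.33e-06. Of 44 proteasome genes 31 were higher and 0 lower by limma (33 and 1 adjusted over the list alone, as at an unadjusted p under 0.05), with a median of 0.39 and a camera adjusted p = 1.01e-06. Both lists had an adjusted p = 0.666 with an estimated correlation. Gclc rose by 1.84 ± 0.19 (n = 4), Gclm by 0.39 ± 0.23 (n = 4), and Gtpx, a glutathione peroxidase gene, by 1.98 ± 0.11 (n = 3). The proteasome subunit genes Rpn5, Prosbeta3, Rpt3 and Rpt2 rose by 1.27 ± 0.11, 1.06 ± 0.09, 0.73 ± 0.19 and 0.68 ± 0.16 (n = 4 each).

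Genes of conjugating enzymes were more often higher than lower in HS-CncC flies. GST genes had 23 of 38 higher and 9 lower, with equal counts adjusted over the list alone, and a median of 0.72. UGT genes had 16 of 31 higher and 7 lower, again with equal counts adjusted over the list alone, and a median of 0.18. Both lists had a camera adjusted p = 0.00164 and an adjusted p = 0.666 with an estimated correlation. GstD7 rose by 4.28 ± 0.13 (n = 4), GstE3 by 4.20 ± 0.13 (n = 4), GstD1 by 2.97 ± 0.11 (n = 3) and GstE1 by 1.32 ± 0.26 (n = 4). P450 genes had 28 of 76 higher and 34 lower (29 and 35 adjusted over the list alone, camera adjusted p = 0.825), and their median was -0.11 while their mean was 0.39. Cyp4d14 rose by 4.01 ± 0.06, the Cyp12d1-d probe by 3.84 ± 0.41, Cyp6w1 by 3.50 ± 0.18, Cyp6a21 by 3.36 ± 0.08 and Cyp6d5 by 3.22 ± 0.12 (n = 4 each). ABC transporter genes had 7 of 16 higher and 6 lower (7 and 6 adjusted over the list alone, 0.581), with Mdr50 at 2.49 ± 0.22 and Mdr49 at -1.53 ± 0.16 (n = 4 each). Esterase and epoxide hydrolase genes had 8 of 19 higher and 4 lower (8 and 4 adjusted over the list alone, 0.451), with Jheh2 at 3.71 ± 0.10 (n = 3). Hr96 was again not called (-0.00 ± 0.26, n = 4, adjusted p = 0.994).

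Immune genes fell and muscle genes rose in HS-CncC flies. Of 36 antimicrobial and immune genes 28 were lower and 3 higher, with equal counts adjusted over the list alone, a median of -0.98 and a camera adjusted p = 9.77e-05. Of 22 muscle genes 17 were higher and 1 lower (17 and 2 adjusted over the list alone), with a median of 0.41 and a camera adjusted p = 0.000343. Both lists had an adjusted p = 0.666 with an estimated correlation. PGRP-LB, which encodes a peptidoglycan amidase that dampens immune signalling, gave 3.02 ± 0.16 (n = 4) at the probe used and -0.37 ± 0.12 at a probe of another transcript. With no background subtraction its value was -0.31, near that of the other probe. The brightest probe was chosen anew under each processing, so this value may be that of the other probe. The flight muscle genes fln, Act88F and TpnC4 rose by 2.93 ± 0.48 (n = 4), 2.58 ± 0.65 (n = 4) and 2.42 ± 0.18 (n = 3). Of 12 hemocyte markers 6 were higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.334), with the clotting gene Hml at 1.58 ± 0.07 and the receptor gene NimC1 at -1.52 ± 0.24 (n = 4 each). Of 6 Turandot genes, which encode secreted stress peptides, 0 were higher and 4 lower by limma, with equal counts adjusted over the list alone and at an unadjusted p under 0.05. TotX was at -2.19 ± 0.75 (n = 4). The calls of TotA, TotC and TotM were lost with an offset of 0 (0.079, 0.113 and 0.0937), with median centring (0.255, 0.182 and 0.0924), with a trend and a robust fit (0.177, 0.241 and 0.174) and with all 8 arrays in one fit (0.0768, 0.0955 and 0.0586). Those of TotC and TotM were also lost with the mean over probes (0.192 and 0.0622), that of TotC with the processed intensities and the deposited table (0.0598 each) and without array 1 (0.0546), and that of TotM without array 2 (0.1) or array 3 (0.0891). Too few members had complete values for the list test.

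Several fat body and metabolic genes fell in HS-CncC flies, and whether their lists passed depended on the processing. Of 11 fat body genes 1 was higher and 5 lower, with equal counts adjusted over the list alone, a median of -0.48 and a camera adjusted p = 0.0559. The fat body list passed, again downward, with no background subtraction (0.0123), the processed intensities or the deposited table (0.0138 with each), the mean local background (0.015), median centring (0.0173) and an offset of 0 (0.0354). It also passed without the filter on dim probes (0.0318), with both channels well above background on all arrays (0.0217), and without array 2 (0.0477) or array 4 (0.0346). Genes that fell included Obp99b (-2.52 ± 0.21, n = 4), the storage protein gene Lsp1beta (-1.95 ± 0.36, n = 4) and apolpp, the lipophorin precursor gene (-1.81 ± 0.09, n = 3). Lipogenic genes had 6 of 16 higher and 8 lower (6 and 8 adjusted over the list alone, 0.825). FASN3, AcCoAS, FASN1, ACC and Desat1 fell by 3.16 ± 0.54, 2.35 ± 0.37, 1.97 ± 0.31, 1.39 ± 0.29 and 1.15 ± 0.10. Fasting-induced genes had 4 of 15 higher and 8 lower (4 and 8 adjusted over the list alone, 0.179), with Pepck1 at -1.12 ± 0.26 (n = 4), and their list passed without the filter on dim probes (0.0399). Digestive enzyme genes had 12 of 47 higher and 21 lower (12 and 21 adjusted over the list alone, 0.0526), with betaTry at 4.13 ± 0.25 (n = 3) and gammaTry at -2.31 ± 0.09 (n = 4). The digestive enzyme list, with a median of -0.25, passed without the filter on dim probes (0.00206), with the mean over probes (0.0366) or the mean local background (0.0416), and without array 3 (0.0183) or array 4 (0.0397).

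Of 92 ribosomal protein genes 7 were higher and 41 lower in HS-CncC flies, with equal counts adjusted over the list alone and a camera adjusted p = 0.0424. They had an adjusted p = 0.8 with an estimated correlation. Their median of -0.16 became 0.66 with median centring, and the preset call was lost without array 2 (0.0642), without array 4 (0.165), with no background subtraction (0.0572) and with an offset of 0 (0.0753). With median centring the list passed upward (4.76e-13). Heat shock genes had 11 of 19 higher and 3 lower (13 and 3 adjusted over the list alone, camera adjusted p = 0.0823), and the preset test passed without array 2 (0.000655) and with median centring (0.00361). The chaperone gene Hsp22 was at 1.43 ± 0.74 (n = 4), with 0.33 on array 2. Eye genes had 10 of 21 higher and 3 lower (10 and 3 adjusted over the list alone, 0.0631), with the opsin gene Rh6 at 2.98 ± 0.13 (n = 4), and their list passed with an offset of 0 (0.0414) and with median centring (0.000847).

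The remaining lists did not pass camera in HS-CncC flies with loess, and those of testis and accessory gland genes passed upward with median centring. Testis genes had 11 of 26 higher and 6 lower (12 and 8 adjusted over the list alone, camera adjusted p = 0.314), with a median of 0.12 that became 0.59 with median centring (0.00355). Accessory gland genes had 4 of 25 higher and 11 lower (5 and 12, 0.314), with a median of -0.18 that became 0.24 with median centring (0.00733). Clock genes had 4 of 11 higher and 4 lower (4 and 5, 0.912), with the clock output gene to at 2.65 ± 0.27 (n = 4). Ecdysone response genes had 3 of 15 higher and 9 lower (3 and 9, 0.145), and activity-regulated genes 2 of 10 and 5 (2 and 5, 0.31). Ovary and yolk genes had 2 of 20 higher and 1 lower (2 and 1, 0.882), and Malpighian tubule genes 4 of 14 and 7 (4 and 7, 0.473). Median, mean and test differed in sign for the P450, ABC transporter, clock and ovary lists.

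The calls of both comparisons were then set against each other. Cyp6a8, Cyp6a2, GstD2, GstD7, Jheh1 and Keap1 were among the 80 features at least 2-fold higher in both, out of 126 with PB, where independent calls would give 3.7. FASN1 (-1.95 and -1.97), ACC (-1.38 and -1.39) and phu (-3.28 and -3.15) fell in both. A difference between the sets was not detectable for FASN1 (0.02, adjusted p = 0.948), ACC (0.01, adjusted p = 0.98) or phu (-0.13, adjusted p = 0.731). Over 18127 features tested in both, 1005 were higher in both, against 420.6 for independent calls, and 1221 lower in both, against 706.1. A further 227 were higher with PB and lower in HS-CncC flies, against 500.4, and 462 the reverse, against 593.4. Across features, which are not independent replicates, the log2 ratios had a Pearson r of 0.401 and a Spearman rho of 0.348. Over the 7567 features called in neither comparison r was 0.218. The sets had different control samples but 1 dye orientation. The shared calls fell to 296 higher and 424 lower without PB array 2, 367 and 551 without array 3, and 548 and 800 without array 4, while without the filter on dim probes they were 2034 and 1365. With median centring 1804 were shared higher and 870 shared lower, so that the larger group changed.

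**Figure D4:**
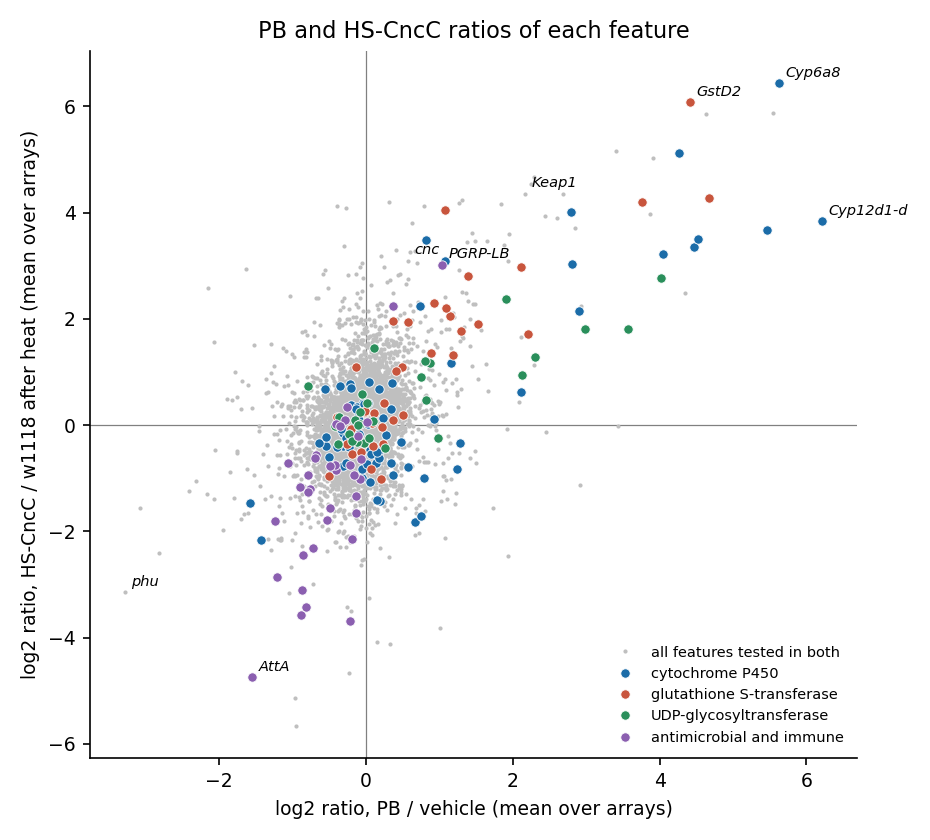
Log2 ratio with PB (horizontal) against log2 ratio in HS-CncC flies (vertical) for each of 18127 features, each the mean over its arrays, with P450, GST, UGT and immune genes coloured and all others grey. Cyp6a8 lay at 5.63 and 6.44, and the Pearson correlation over all features was 0.401.

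The last comparison tested whether the PB and HS-CncC ratios differed. Keap1 and the cnc probe used rose less with PB, by a log2 of -2.19 (adjusted p = 3.89e-08) and -2.52 (adjusted p = 1.58e-06), as did MsrA (-1.65) and Jheh1 (-1.75). The Cyp12d1-d probe (2.38, adjusted p = 5.65e-06), Ugt37A2 (1.77), Ugt35C1 (1.26) and Cyp6a21 (1.11) rose more with PB. Cyp6g1 rose more with PB at the probe used (adjusted p = 4.59e-06), and the difference turned to -3.58 for the mean of its probes. Pepck1, which rose with PB and fell in HS-CncC flies, stood 4.04 higher with PB (adjusted p = 1.33e-07). The flight muscle genes Act88F and fln, which fell with PB and rose in HS-CncC flies, differed by -4.74 and -4.56. All PB arrays lay on 1 slide scanned in 1 session and all HS-CncC arrays on another, so slide, scan session and set cannot be told apart in these differences.

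In the test of the difference 3139 of 18824 features were higher and 2934 lower with PB than in HS-CncC flies, or 32.3%, with 969 and 1396 at least 1.5-fold apart. With median centring 2768 were higher and 3013 lower. Among features that passed this test, the largest positive differences were those of tobi (4.81), CG14120 (4.70), CG32117 (4.45), CG12934 (4.44), CG15263 (4.40) and the ornithine aminotransferase gene Oat (4.24). Their order and size depended on the processing. Over the alternatives CG14120, CG32117, CG15263 and Oat reached 8.20, 8.09, 8.11 and 7.96, whereas tobi stayed between 4.28 and 5.00. In the HS-CncC set both channels were well above background on 1 of 4 arrays for CG14120 and on 2 for CG32117. The largest negative differences were those of CG31226 (-7.62), TC255103 (-7.40), lambdaTry (-5.27), RE09036 (-5.24), Prx3 (-5.02) and Act88F (-4.74), of which only Act88F was far enough above background to be tested with PB. Features well above background in both channels on at least 6 of the 8 arrays also included IP14124 (4.17), betaTry (-4.53), CG8858 (-4.37), the autophagy gene Atg7 (-3.88) and the transporter gene MFS1 (-3.68). The IP14124 probe (3L, 12882242 to 12882301) overlaps that of CG14120 (12882190 to 12882249), so both may read 1 locus. Of the features called the same way in both comparisons, 343 of the 1005 higher ones, or 34.1%, and 457 of the 1221 lower ones, or 37.4%, differed in size by this test.

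Of 24 lists tested for the difference 6 passed camera with the preset correlation and 0 with an estimated correlation, and at an unadjusted p under 0.05 the numbers were 7 and 3. Antioxidant genes stood lower with PB, with 3 of 35 higher and 17 lower (3 and 18 adjusted over the list alone) and a camera adjusted p = 1.96e-05. Muscle genes also stood lower, with 2 of 22 higher and 16 lower (2 and 17 adjusted over the list alone) and a camera adjusted p = 1.23e-05. Both had an adjusted p = 0.244 with an estimated correlation. Proteasome genes stood lower with PB, with 1 of 44 higher and 31 lower (1 and 31 adjusted over the list alone) and a camera adjusted p = 1.96e-05. Hemocyte markers stood lower as well, with 3 of 12 higher and 8 lower (4 and 8 adjusted over the list alone) and a camera adjusted p = 0.016. Both had an adjusted p = 0.416 with an estimated correlation. Ribosomal protein genes stood higher with PB, with 64 of 92 higher and 0 lower by limma (69 and 0 adjusted over the list alone, 74 and 0 at an unadjusted p under 0.05) and a camera adjusted p = 4.36e-10. They had an adjusted p = 0.416 with an estimated correlation, and with median centring the preset call was lost (0.0829) as the median difference fell from 0.35 to 0.0838. Fat body genes stood higher, with 6 of 11 higher and 0 lower by limma (7 and 1 adjusted over the list alone, as at an unadjusted p under 0.05) and a camera adjusted p = 0.00959. They had an adjusted p = 0.244 with an estimated correlation. The P450, GST and UGT lists did not pass (0.177, 0.286 and 0.801). The antimicrobial and immune list, at 0.0988, passed with an offset of 0 (0.0446), without the filter on dim probes (0.0422), without PB array 3 (0.0143) and without HS-CncC array 1 (0.0447) or 2 (0.023). The testis list passed without PB array 1 (0.0279) and the heat shock list without HS-CncC array 2 (0.0322), against 0.356 for each with all arrays.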

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

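Of the tests in this part, only those of a dye bias and of normalization in the PB set alone, both for the ribosomal protein shift, were chosen after the result was seen. For each group of 4 arrays the gap between the most extreme array and its nearest neighbour was divided by the range. In 15 of 331 groups, or 4.5%, this ratio exceeded the 95% critical value of Dixon for 4 values, and chance gives about 1 in 20.

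The arrays numbered 1 stood apart in their count of outlier spots, with 862 against a mean of 65.7 on the other PB arrays (ratio 0.972) and 1688 against 125 on the other HS-CncC arrays (ratio 0.975). In the PB set, array 1 also gave the least negative ratio of apolpp, the lipophorin precursor gene, with -0.23 against a mean of -0.56 (0.931). Array 1 gave the lowest ratio of the testis gene Mst84Dc, with 0.15 against 0.52 (0.875), and the lowest median of the testis list, with -0.03 against 0.26 (0.898). The antioxidant list had its highest median there, with 0.22 against 0.02 (0.922). The clock gene cry was least negative on PB array 4, with -0.16 against -0.38 (0.843), and the unnamed feature TC243295 was highest there, with 0.61 against 0.34 (0.854).

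In the HS-CncC set, array 1 gave the lowest ratios of CG8858, with 3.70 against a mean of 4.23 (0.873), and of GstD7, with 4.10 against 4.35 (0.919). Array 2 gave the lowest ratio of the chaperone gene Hsp22, with 0.33 against 1.80 (0.911). Array 4 gave the lowest ratio of the unnamed feature TC240329, with 0.90 against 5.44 (0.869). It also gave the lowest ratios of CG9837, with -1.31 against -0.96 (0.834), of Fst, a frost-induced gene, with -4.24 against -1.16 (0.833), and of ninaD, a scavenger receptor gene of carotenoid uptake, with -1.77 against -1.23 (0.833).

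The calls with PB and in HS-CncC flies overlapped in direction. Base composition of the probes is argued against as the cause, because 99.5% of the correlation was left after its trend was removed. A dye bias common to all arrays would leave few of the shared calls different between the sets, and 35.9% of them passed the test of the difference. That share excludes nothing, although over 20% had been set as the bound, because 32.3% of all features passed the same test, and dye bias and a shared response cannot be told apart without a dye swap. A shared detoxification and antioxidant response is consistent with the correlation of 0.792 over the 178 genes of the P450, GST, UGT and antioxidant lists, above the 0.066 to 0.711 that held the central 95% of 10000 lists matched on brightness.

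With loess, 44 of 92 ribosomal protein genes were higher with PB and 41 of 92 lower in HS-CncC flies, though neither list call held with an estimated correlation (0.666 and 0.8). Base composition is argued against, because at least 106.8% of the list median was left in either comparison once it was removed. A dye bias alone would give the list 1 sign in both sets. With loess the signs were opposite and the median difference was 0.35 (camera adjusted p = 4.36e-10, or 0.416 with an estimated correlation). With median centring both medians were positive and the difference was 0.0838 (0.0829), so a dye bias cannot be told apart from a change in these genes. With PB the median lay at percentile 100 of 10000 lists matched on brightness with loess (0.17 against -0.05 to 0.10 for the central 95%). It did so with median centring as well (0.72 against 0.29 to 0.46). These percentiles cannot exclude normalization of bright spots as the cause. The lists were drawn as independent genes, whereas the estimated correlation among ribosomal protein genes with PB was 0.34. In HS-CncC flies normalization of bright spots cannot be told apart from a change in these genes. There the median lay at percentile 0.44 with loess but at 78.1 with median centring, where it turned from -0.16 to 0.66.

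In HS-CncC flies 49.6% of the features tested were called. A smaller spread between these arrays is argued against, because their median SD was 101% of that of the PB arrays. Whether 1 chromosome arm that differs between the strains contributed cannot be told apart from a change across the genome: the share of features changed 2-fold was 7.01% on 2R and 3.53% on X, a ratio of 1.99 that lay between the bounds set. Genetic background, dye and CncC itself stay open as explanations, as the design varies them together.

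The sign of each array's ratio was turned in every combination to see how many calls other groupings give. For PB, 1 of 8 sign patterns gave as many calls, the labelled one with 4500, and the highest of the others gave 6. For HS-CncC, 1 of 8 gave as many, the labelled one with 9076, and the highest of the others gave 18. With 8 patterns no share under 0.05 can be reached in either comparison. For the difference between PB and HS-CncC, 1 of 35 splits gave as many calls, the labelled one with 6073 against 2 for the highest other. That share of 0.0286 is the smallest that 35 splits can give, so a chance split is unlikely but not excluded. Every other split mixes the sets, which by itself leaves few calls. Slide and scan session divide the arrays as the labels do.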

How the results depend on the processing

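The mean in place of the median of the local background, and named features only, were chosen as alternatives after seeing the data, and the others before. Quantile normalization of average intensity turned or ended no call among 173 named genes with PB, 182 in HS-CncC flies, 49 list tests of single comparisons and 24 of the difference. It leaves the ratio of each probe as it was and can only alter which probe stands for a gene, so little change was possible. Without HS-CncC array 1, 174 of 182 named genes kept their direction and side of the threshold in HS-CncC flies, and without PB array 2, 132 of 164 did with PB, 32 being no longer called. The cnc ratio in HS-CncC flies was 0.90 in place of 3.10 with the mean over its probes. The red channel, with the higher background, limited the dim features, and no spot was saturated. The cause of the changes below was not tested, except that stricter thresholds leave fewer calls by construction. The brightest probe of a gene was chosen anew under each processing. A value that turned with the background correction, such as that of PGRP-LB, may therefore be that of another probe.

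Leaving out each array gave 459 to 3139 features higher and 891 to 3210 lower with PB. The shared calls ran from 296 to 1502 higher and from 424 to 1519 lower, and the correlation of the ratios from 0.361 to 0.403. Without PB array 1 the PB counts were 3139 and 3210, without array 2 they were 459 and 891, without array 3 598 and 1163, and without array 4 958 and 1744. Without PB array 2, 3 or 4 in turn the shared calls were 296, 367 and 548 higher and 424, 551 and 800 lower. Without HS-CncC arrays the counts in HS-CncC flies ran from 3277 to 3478 higher and from 3873 to 4088 lower.

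With no background subtraction 2981 features were higher with PB, and 1784 were shared higher and 1896 shared lower. PGRP-LB turned to -0.40 with PB and -0.31 in HS-CncC flies, and the eggshell gene Vm32E to 0.0156 with PB and 0.27 for the difference. With the processed intensities, and with the deposited log2 table alike, 2935 features were higher with PB, 5134 were higher in the difference, 1571 were shared higher and the correlation was 0.336. There PGRP-LB was at -0.40 and -0.35, Vm32E at 0.17 with PB and 0.81 for the difference, and dec, an eggshell gene, at 0.0208 in HS-CncC flies, while the difference of Mos turned to 0.81. With an offset of 0, 1244 features were higher with PB, and PGRP-LB was at -0.37, -0.43 and, for the difference, 0.0628. With the mean local background 3169 features were higher with PB and 1863 shared higher.

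With median centring in place of loess 1804 features were shared higher and 870 shared lower, the correlation was 0.470 and 25 list tests passed. The medians of the muscle list with PB and of the ribosomal protein and accessory gland lists in HS-CncC flies turned to 0.28, 0.66 and 0.24, each past the threshold, and a further 7 list tests passed without turning. Of the list tests of the difference, that of ribosomal proteins was lost (0.0829). With PB, Mlc2, Prosbeta7, RpL35 and RpS16 turned to 0.52, 0.0938, 0.0833 and 0.36. In HS-CncC flies, Act57B, lncRNA:Hsromega, RpL35, RpS16 and sug turned to 0.74, 0.74, 0.087, 0.19 and 0.37, TC243295 to -0.013, and the difference of Arr2 to -0.0069. With the mean over probes, Arr2 was at -0.13, -0.0173 and, for the difference, -0.11, the difference of Cyp6g1 at -3.58, and trpl at -0.39 in HS-CncC flies and 0.42 for the difference. There cwo and deltaTry were at 0.0598 and -0.27 in HS-CncC flies.

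Without the filter on dim probes 3737 features were higher with PB, 6323 higher in HS-CncC flies and 2034 shared higher. With a 1.5-fold threshold the counts were 248 higher and 431 lower with PB, 1206 and 1335 in HS-CncC flies, 969 and 1396 for the difference, and 142 and 139 shared. At an adjusted p under 0.01 they were 562 and 973 with PB, 3210 lower in HS-CncC flies, 1963 higher for the difference, and 331 and 389 shared. Of the list tests of single comparisons 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 27 with fry, where the ABC transporter list with PB (median -0.10) passed in the other direction. With fry 4 of the 16 preset calls were lost. They were the immune, testis and heat shock lists with PB (fry adjusted p = 0.0723, 0.148 and 0.285) and ribosomal proteins in HS-CncC flies (0.0624).

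The replicate numbers did not pair the arrays, as the correlations of same-numbered deviations were 0.007, 0.051, -0.11 and 0.1, and only PB array 2 and PB array 4 correlated best with the HS-CncC array of the same number. With the replicate number as a block the difference gave 2813 features higher and 2679 lower, against 3139 and 2934.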

Other observations

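The tests of the elongase family and of the block on arm 2R were chosen after the results were seen, and that of probes on both sides of 0 before. For the ecdysteroid kinase-like family the bounds were written before the test, but the family was added after values of members had been seen. Fatty acid elongase genes, which extend fatty acid chains and lie outside the lists, were mostly lower with PB and mostly higher in HS-CncC flies. Of 20 measured, 12 were lower and 1 higher with PB, with a median log2 of -0.41, and of 19 measured, 13 were higher and 2 lower in HS-CncC flies, with a median of 0.49. Neither direction turned under any scaling tried, the PB median running from -0.76 to -0.38 and the HS-CncC median from 0.48 to 0.85. The first members noticed were CG9458 (-2.07 ± 0.36 with PB and 1.57 ± 0.35 in HS-CncC flies, n = 4 each), CG6660 (-2.06 ± 0.35 and -0.47 ± 0.33), CG16904 (-1.89 ± 0.28 and 0.49 ± 0.35) and CG9459 (-1.69 ± 0.39 and 0.84 ± 0.24). Over the 16 members outside these the PB median was -0.25, against -0.14 to 0.12 for the central 95% of 10000 lists matched on brightness (percentile 0.03). A family-wide lower expression with PB is a hypothesis that this value is consistent with.

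Ecdysteroid kinase-like genes, a large family known from their predicted kinase domain and taken here from clade names among the synonyms of the reference table, changed often with PB. Of 49 measured, 22 were higher and 6 lower with PB, with a median of 0.22, and of 48 measured, 29 were higher and 13 lower in HS-CncC flies, with a median of 0.43. Members chosen after their values were seen include CG31288 (2.94 ± 0.16 with PB and 2.25 ± 0.11 in HS-CncC flies, n = 4 each), CG10560 (2.44 ± 0.27 and 3.94 ± 0.16) and CG16898 (1.05 ± 0.19 and -1.24 ± 0.70). Among the 46 members outside those named for PB, 54.3% were called with PB, against 15.2% to 41.3% for the central 95% of 10000 lists matched on brightness (percentile 99.98). These 46 include CG31288, CG10560 and CG16898. The family may respond to PB beyond the members named by the rule, as a hypothesis.

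The control samples of the sets differ in treatment, since the w1118 flies of the HS-CncC set had been heated, and in slide, so the levels below are values and not a test. In the green channel the log2 level of Hsp70Bc was 8.72 ± 0.39 in vehicle-fed and 11.77 ± 0.92 in heated w1118 flies (SD, n = 4 each), and Hsp70Bb, Hsp23 and Hsp22 differed by 2.70, 1.70 and 0.06. The yolk protein gene Yp1 was at 6.84 ± 0.11 in the vehicle-fed males and 7.17 ± 0.97 in the heated flies, whose sex the labels do not give. Over the testis list, heated minus vehicle levels ran from -0.03 (mia) to 0.30 (topi). Over the ovary and yolk list they ran from -0.52 (grk) to 0.37 (Cp36). These levels argue against heated w1118 samples made up mostly of females.

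Probes of 1 transcript disagreed in HS-CncC flies in a way that may come from sequence differences between the strains. Among transcripts with at least 2 probes at least 0.5 log2 from 0, the share with probes on both sides of 0 was 1.4% in HS-CncC flies (8 of 564) and 0.6% with PB (1 of 175), a ratio of 2.48 that the counts are too few to separate from chance (Fisher's exact test, p = 0.694). The share of transcripts with probes at least 1 log2 apart was 4.18 times as high on 2R as on the other arms (Fisher's exact p = 4.19e-08). Among transcripts whose brightest probe lay within 0.5 of 0 it was 6.82 times as high (7 of 671 against 4 of 2614, Fisher's exact p = 0.0022). Between 6 and 12 Mb of 2R 21 of 252 transcripts, or 8.33%, were apart, against 40 of 3927, or 1.02%, elsewhere, and with PB 1 of 250 in that region was. The windows from 6 to 8, 8 to 10 and 10 to 12 Mb had the highest shares on any arm (9%, 9.6% and 6.6%). This contrast therefore describes these data and is not a test. A block of 2R that differs between HS-CncC and w1118 is a candidate explanation. It would touch Cyp6g1 at 8074216 to 8075931, deltaTry and the other genes there, whatever CncC does. Genes and features named above with probes there include Cyp6a8, Cyp6a21, Cyp12d1-d, Cyp12d1-p, AttA, AttC, BaraA1, CG12934, CG8858, Mdr49 and Mdr50. The trypsin gene lambdaTry, CG30049 and AT01131 have probes there too, as does the attacin gene AttB. The HS-CncC ratios of these genes, and of others in that region that are not listed, carry the same limit.

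Of 60 features at least 8-fold higher in HS-CncC flies, 5 were not well above background in any channel of the PB arrays. They were lambdaTry, which lies in that part of 2R (7225145 to 7225204), Prx3 on 3R (13371057 to 13371116) and the unnamed features TC240329, A_09_P224510 and EC196523. On array 4 alone TC240329 was at 0.90 and A_09_P224510 at 1.00, far below their means of 4.31 and 3.44. Prx3 was well above background in the heated w1118 sample on 4 of 4 arrays.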
